A study of Mus musculus with 24 samples.

How the data were processed

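The series holds 24 Affymetrix arrays of mouse lung RNA in 6 groups of 4. Per the labels, frozen lung was extracted with Qiagen RNeasy kits and biotinylated cRNA was made from 2 ug of total RNA. The deposited values are 1 intensity per probe set and array on a linear scale, which the authors computed with the Affymetrix MAS5 algorithm. The version of MAS5 is not given in the sources used here. The mean signal of each array without its lowest and highest 2% lay between 500.1 and 500.2, and the array medians lay between 182 and 243, so the arrays had already been scaled to a common trimmed mean.

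Of 22690 probe sets, 64 Affymetrix control probe sets were set aside and 22626 were kept. By the annotation deposited with the array, 20380 of these name 1 gene, 691 name several genes and 1555 name none. Signals were taken to log2 without a pseudocount. A probe set was tested when its mean log2 signal lay above the 40th percentile, a geometric mean signal of 138, which left 13576 probe sets, of which 12489 name 1 gene, 438 several and 649 none. They represent 8315 genes, each spoken for by its probe set with the highest mean signal. Nqo1, Il4, Il13, Ccl11 and Clca1 are on the array but lay below this limit and were not tested.

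A linear model with 1 mean per group was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a mean-dependent trend). The moderated t-test is two-sided, and p-values were adjusted by the Benjamini-Hochberg (BH) method over the tested probe sets of each of 11 comparisons. A probe set was called at adjusted p < 0.05. Probe sets with unadjusted p < 0.05 in limma were counted as well. About 679 of them, 5% of the tested probe sets, would be expected without any effect. A value after ± is a standard error (SE) unless it is said to be a standard deviation (SD). Gene lists were taken from general knowledge of pathways and cell types, 46 in number, of which 45 had at least 5 tested genes; the 46th, of thymus markers, had 2 and was not tested. Shifts of lists were tested with camera at its preset correlation of 0.01 against all other tested genes and adjusted over the lists. Each call was set beside camera with the correlation estimated from the data. Members of a list were also adjusted over the list alone. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for the tables and figures.

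Genes are named by a rule fixed in advance. It takes up to 10 largest rises and 10 largest falls among called genes whose values in the compared groups do not overlap; for averages and interactions the call alone is asked for. Where fewer than 5 genes are called, the 5 genes with the smallest p are taken. From each list described, up to 4 members with the smallest p are taken. Cyp1a1, Cyp1b1, Hmox1, Gclc, Saa3, Mt1 and Mt2 are named for exhaust, and Chil3 and Retnla for OVA, whatever their values. Clone names were passed over, Fyttd1 is named as a called gene whose values overlap, and Hp is named beside the other members of its list.

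The groups, comparisons, model, filter, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives named then were quantile normalization, scaling to the median, no filter, a stricter filter at the 60th percentile, a pseudocount of 47.0, fitting only the groups compared, array weights, no trend, 1 probe set per gene, the replicate number as a block and leaving out each array. The following 4 fits were added after the values had been seen: the log2 3'/5' ratio of the Gapdh and actin control probe sets as a covariate, the signal of the B1 repeat control as a covariate, both together, and the 3'/5' covariate without DE2000_OVA replicate 4. The 3'/5' covariate is the mean of the Gapdh and actin ratios.

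The fit was tested on simulated data made from the spread of the real arrays, with 50 probe sets changed at each size. In the comparison of DE 2000 with air in saline it recovered 26% of changes of 1.5-fold, 74% of 2-fold, 90% of 3-fold and 98% of 4-fold, with 11 false calls among 13376 unchanged probe sets. The noise was drawn independently for each probe set, with the same spread in all groups. The real arrays share variation across probe sets and differ in spread between groups, so these rates may not hold for them. Data simulated with a slope on the 3'/5' ratio and no effect of ovalbumin gave 6075 calls for ovalbumin without the covariate and 0 with it. That slope was a straight line on the same ratio that was then fitted, so the 0 followed from how the data were made. It checks the fit only, not whether the ratio captures all degradation in the real arrays. The replicate numbers were checked for pairing between groups: over 60 group and number pairs the residual correlation averaged 0.03, between -0.43 and 0.59, and they were not used as pairs.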

Results

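Lung RNA was profiled in mice that breathed filtered air or diesel exhaust at 500 ug/m3 (DE 500) or 2000 ug/m3 (DE 2000) for 4 hours a day on 5 days, and that received saline or ovalbumin (OVA, 100 ug) on 3 days. The 6 groups had 4 arrays each, a number that limits the precision of every comparison. The labels do not state whether the replicates of a group are separate animals. Log2 signals of pairs of arrays correlated between 0.81 and 0.98. Gene values are log2 fold changes ± SE, and adjusted p-values come from limma.

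The OVA and saline arrays differed in the evenness of signal along the transcript. The log2 ratio of the 3' to the 5' control probe set of Gapdh, a glycolytic enzyme, was 2.05 ± 1.47 (SD, n = 12) in saline and -0.03 ± 0.69 in OVA, a difference of -2.07 (exact permutation test within exposures, p = 5.25e-05, BH-adjusted over 6 measures 0.000105). The same ratio of actin, the cytoskeletal protein, differed by -1.19 (exact permutation test, p = 0.00211). The probe set for B1, a short repeat carried in many unspliced transcripts, gave 12.98 ± 0.53 in saline and 11.55 ± 0.46 in OVA (exact permutation test, p = 5.83e-06, the smallest possible). The hybridization controls, transcripts added to every sample, differed by -0.37 (exact permutation test, p = 0.00573). Within saline, DE500_saline replicates 1 and 4 had Gapdh ratios of 4.91 and 4.34 and replicates 2 and 3 had 0.36 and 0.08. In OVA, DE2000_OVA replicate 4 stood alone at 2.09. Between exhaust and air, the mean ratio of Gapdh and actin and the B1 signal gave p from 0.314 to 0.886 within the arms (exact permutation tests, BH-adjusted p = 0.886 for all 8 comparisons). With 4 arrays against 4 the smallest possible p is 0.0286, or 0.229 after adjustment for a single difference, so a lone difference could not have passed.

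**Figure D1:**
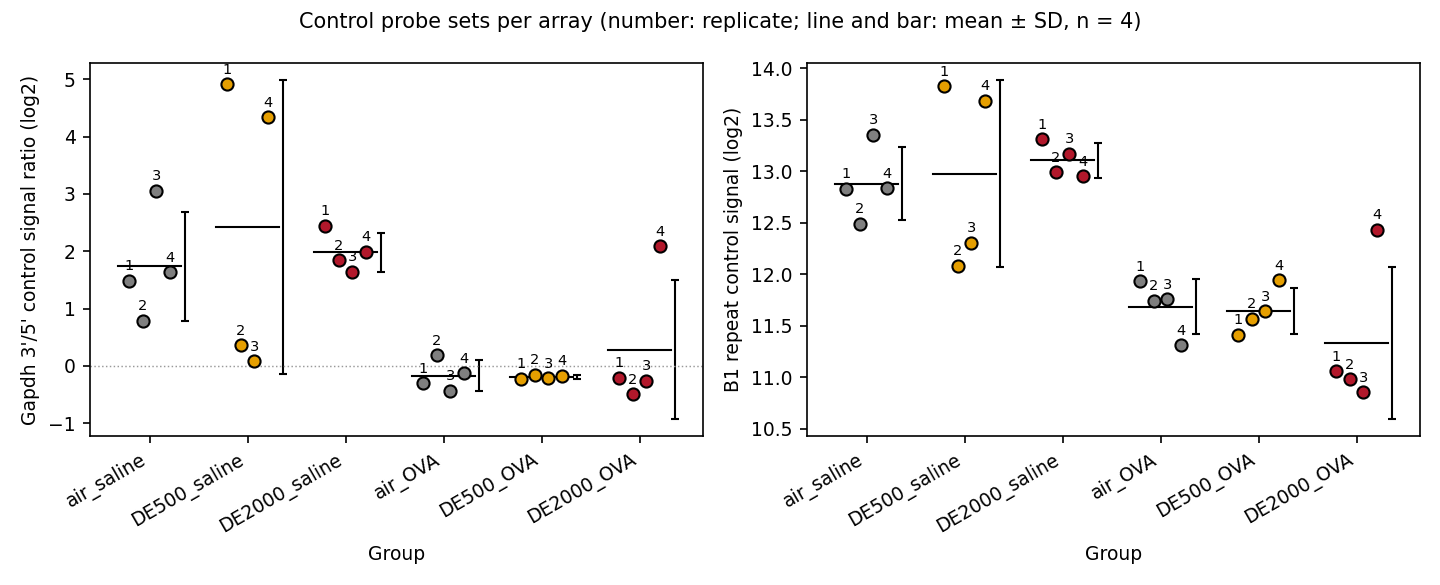
Log2 3'/5' ratio of Gapdh control probe sets and log2 signal of the B1 repeat (y axes) in each array by group (x axis); points are arrays, bars the mean ± SD of 4. The ratio averaged 2.05 in saline and -0.03 in OVA.

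Exhaust at 2000 ug/m3 raised 9 genes in saline-treated mice. Saa3, a serum amyloid A made locally in acute inflammation, rose 6.65-fold (2.73 ± 0.48, adjusted p = 0.0179; log2 signal 7.42 ± 0.45 in air and 10.15 ± 0.27 in DE 2000, SD, n = 4 each). Cd177, a surface glycoprotein of neutrophils, rose 5.24-fold (2.39 ± 0.30, adjusted p = 0.000683; 7.11 ± 0.39 against 9.50 ± 0.43). Pigr, the receptor that carries IgA across epithelium, rose 2.69-fold (1.43 ± 0.22, adjusted p = 0.00394), and its second probe set rose by 1.64 (adjusted p = 0.00205). Lcn2, a lipocalin that withholds iron from bacteria, rose by 0.97 ± 0.18 (adjusted p = 0.0179).

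Other genes that rose with DE 2000 in saline were Tbx4, a transcription factor of lung mesenchyme (0.78 ± 0.15, adjusted p = 0.0320), Tmod3, which caps actin filaments (1.0 ± 0.20, adjusted p = 0.0337), Pgap2, which remodels lipid anchors of proteins (1.15 ± 0.22, adjusted p = 0.0228), and the mRNA export factor Fyttd1 (1.53, adjusted p = 0.0455), whose values overlapped between the groups. The remaining probe sets of Tmod3 (-0.33 and 0.24) and Pgap2 (-0.45 and 0.14) were not called. A pair of probe sets of Cp, the copper-carrying ferroxidase ceruloplasmin, rose by 1.82 (adjusted p = 0.00205) and 0.96 (adjusted p = 0.0328), while its most strongly expressed probe set gave 1.14 ± 0.27 (adjusted p = 0.113). Targets of the aryl hydrocarbon receptor did not pass: Cyp1a1, which oxidizes polycyclic hydrocarbons, gave -0.39 ± 0.28 and Cyp1b1 -0.07 ± 0.20 (adjusted p = 1.0 for Cyp1a1). The oxidant-response genes Gclc, for glutathione synthesis, and Hmox1, for heme breakdown, gave 0.62 ± 0.19 (adjusted p = 0.297) and 0.43 ± 0.47, and the metal-binding Mt1 and Mt2 gave -0.35 ± 0.26 and -0.38 ± 0.22.

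Of 12 neutrophil markers all 12 had values above 0 in this comparison (median 0.30, camera adjusted p = 3.79e-06; adjusted p = 0.0253 with an estimated correlation). None was called over all genes and 5 were called when adjusted over the list alone. Among the members were Pglyrp1, a granule protein that binds bacterial walls (1.03 ± 0.29), the calprotectin subunits S100a8 (1.0 ± 0.31) and S100a9 (1.13 ± 0.32), and the gelatinase Mmp9 (0.52 ± 0.16). The list of acute phase and metallothionein genes shifted up (9 of 12 above 0, median 0.36, camera adjusted p = 5.05e-06, or 0.0253 with an estimated correlation). Its metallothioneins Mt1 and Mt2 had values below 0. Of the 12 members, 2 were called over all genes, Saa3 and Lcn2, and 5 over the list alone, including the antibacterial lectin Reg3g (2.76 ± 0.75). Hp, which binds free hemoglobin, gave 0.37 ± 0.15. Glucocorticoid-responsive genes shifted down (4 of 24 above 0, median -0.23, camera adjusted p = 0.0264; adjusted p = 0.782 with an estimated correlation). The phosphatase Dusp1 gave -0.75 ± 0.28 and the kinase Sgk1 -0.39 ± 0.15, while the only called member, Lcn2, rose. Extracellular matrix genes shifted down (10 of 34 above 0, median -0.14, camera adjusted p = 0.0481; adjusted p = 0.617 with an estimated correlation). The fibrillar collagen Col5a2 gave -0.44 ± 0.15 and the beaded-filament collagen Col6a3 -0.39 ± 0.17, while Mmp9 of the same list had a value above 0.

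In all, 20 probe sets rose and 0 fell with DE 2000 in saline, 9 genes by their speaking probe sets, against 807 with unadjusted p < 0.05. With the 3'/5' ratio as a covariate 63 were called, including all 20. Leaving out 1 array gave from 4 to 106 calls, each of the 8 arrays moving the count by over 1.5 times, and array weights gave 138, of which 28 fell. The calls of Cd177 and Pigr held under every alternative, while those of Saa3 (adjusted p from 0.0555 to 0.0925) and Lcn2 (from 0.0587 to 0.112) were lost without air_saline replicate 1 or 2 or any 1 of the DE2000_saline arrays, and those of Tmod3, Pgap2 and Tbx4 also without air_saline replicate 3 and when only the 2 groups were fitted (adjusted p = 0.145, 0.135 and 0.0826). Pgap2 was also lost with the replicate block (0.0607).

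**Figure D2:**
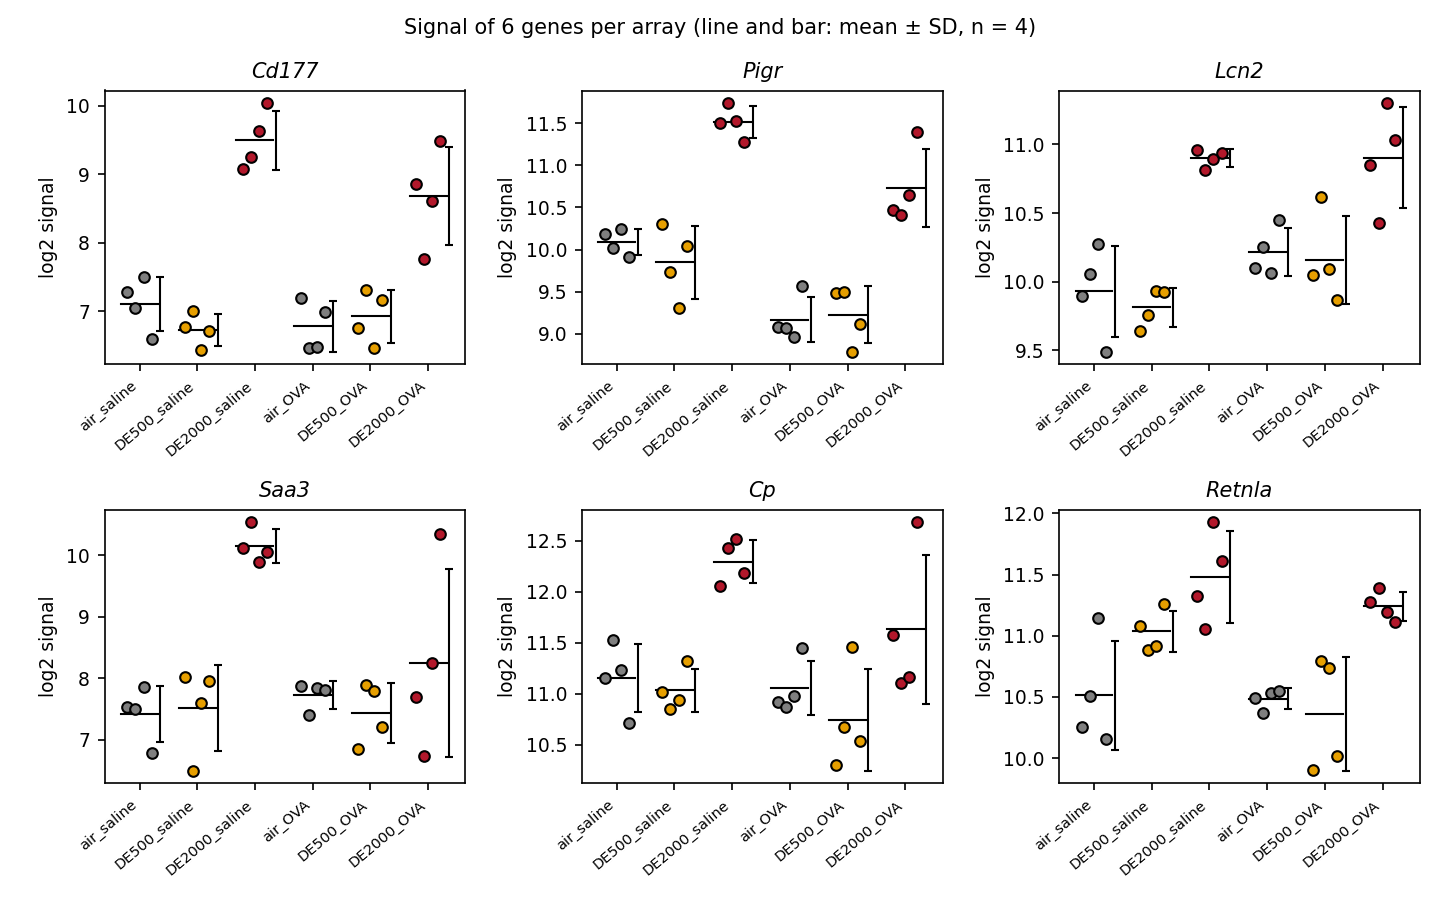
Log2 signal (y axes) of Cd177, Pigr, Lcn2, Saa3, Cp and Retnla in each array by group (x axis); points are arrays and bars the mean ± SD of 4. Cd177 rose by 2.39 with saline and by 1.90 with OVA at 2000 ug/m3.

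Exhaust at 500 ug/m3 changed 1 gene in saline-treated mice. The actin-capping gene Tmod3 rose 2.34-fold (1.22 ± 0.20, adjusted p = 0.0345; 9.09 ± 0.53 in air and 10.31 ± 0.37 in DE 500, SD, n = 4 each), while its other probe sets gave -0.03 and 0.66 and were not called. The next genes by p were Fyttd1 (1.71 ± 0.31), Eif2ak2, the kinase that halts translation on sensing double-stranded RNA (1.23 ± 0.23), Zfp36l1, which speeds mRNA decay (0.74 ± 0.14), and Atp8a1, a phospholipid flippase (1.51 ± 0.30), each at adjusted p = 0.0658. Of the genes that rose at the higher dose, Saa3 gave 0.09 ± 0.48 here, Cd177 -0.38, Pigr -0.24 and Lcn2 -0.12, while Tbx4 gave 0.77, Pgap2 0.77 and a probe set of Cp 1.37. None of these was called, nor were Cyp1a1 (-0.31 ± 0.28), Cyp1b1 (0.05 ± 0.20), Gclc (0.47 ± 0.19), Hmox1 (0.36 ± 0.47), Mt1 (-0.30 ± 0.26) and Mt2 (-0.35 ± 0.22).

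Glucocorticoid-responsive genes shifted down with DE 500 in saline (1 of 24 above 0, median -0.23, camera adjusted p = 0.00128; adjusted p = 0.813 with an estimated correlation). None of them was called over all genes and 1 was called over the list alone, Gadd45g, which arrests growth under stress (-0.81 ± 0.22). The feedback inhibitor Errfi1 gave -0.54 ± 0.23 and the glucocorticoid-induced factor Klf15 -0.59 ± 0.31. Immediate early genes shifted up (14 of 19 above 0, median 0.15, camera adjusted p = 0.0332; adjusted p = 0.813 with an estimated correlation). Among them the transcription factors Klf6 and Jund gave 0.34 ± 0.12 and 0.35 ± 0.15. Oxidative phosphorylation genes shifted down (5 of 39 above 0, median -0.13, camera adjusted p = 0.0332; adjusted p = 0.813 with an estimated correlation). The complex III core subunits Uqcrc1 and Uqcrc2 gave -0.33 ± 0.16 and -0.29 ± 0.11, and under quantile normalization this shift had adjusted p = 0.0817. Of all probe sets 1 was called and 1073 had unadjusted p < 0.05, while 75 were called with the 3'/5' ratio as a covariate and 101 without air_saline replicate 4. The DE500_saline arrays had the widest spread of that ratio, and the call of Tmod3 was lost under median scaling (adjusted p = 0.0585), when only the 2 groups were fitted (adjusted p = 0.902) and without any 1 of air_saline replicates 1, 2 and 3 or DE500_saline replicates 1 and 4 (from 0.121 to 0.303).

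With OVA, exhaust at 2000 ug/m3 again raised Cd177 and Pigr. The neutrophil glycoprotein Cd177 rose 3.73-fold (1.90 ± 0.30, adjusted p = 0.0134; 6.78 ± 0.37 in air and 8.68 ± 0.71 in DE 2000, SD, n = 4 each). The IgA carrier Pigr rose 2.95-fold (1.56 ± 0.22, adjusted p = 0.00385), and its second probe set gave 0.94 (adjusted p = 0.422). Polr2j, a subunit of RNA polymerase II, rose by 0.67 ± 0.12 (adjusted p = 0.0467). The interferon-induced membrane protein Ifitm1 gave 0.77 ± 0.16 (adjusted p = 0.175), the ubiquitin-ligase subunit Fbxw9 -0.88 ± 0.20 (adjusted p = 0.373), and the resistin-like Retnla, made by airway epithelium and macrophages, 0.76 ± 0.21 (adjusted p = 0.492). Saa3 gave 0.52 ± 0.48 (adjusted p = 0.776), and its difference between the arms, the interaction, was -2.21 ± 0.68 (adjusted p = 0.483). Hmox1 gave -0.87 ± 0.47, Gclc 0.12 ± 0.19, Cyp1a1 -0.02 ± 0.28, Mt1 0.38 ± 0.26 and the chitinase-like Chil3 0.25 ± 0.16.

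Circadian clock genes shifted down with DE 2000 in OVA (2 of 15 above 0, median -0.35, camera adjusted p = 8.34e-06; adjusted p = 0.00819 with an estimated correlation). None was called over all genes and 4 were called over the list alone: Nr1d1 (-1.54 ± 0.41) and Nr1d2 (-0.68 ± 0.18), the REV-ERB repressors of the clock, Tef, a clock output factor (-0.35 ± 0.10), and the period gene Per1 (-0.52 ± 0.16). The time of day at which the lungs were taken is not given in the sources used here, and clock genes vary with it. Acute phase genes shifted up (11 of 12 above 0, median 0.31, camera adjusted p = 0.00192; adjusted p = 0.104 with an estimated correlation). Lcn2 gave 0.69 ± 0.18 and Cp 0.58 ± 0.27. Targets of NRF2, the factor that induces antioxidant genes, shifted up (17 of 21 above 0, median 0.18, camera adjusted p = 0.00192; adjusted p = 0.104 with an estimated correlation). None was called, and the thioredoxin Txn1 gave 0.35 ± 0.10 and the aldehyde-reducing Akr1b8 0.42 ± 0.16. Glutathione genes shifted up (21 of 24 above 0, median 0.19, camera adjusted p = 0.000126; adjusted p = 0.104 with an estimated correlation). The transferases Gstt1 and Gstp1 gave 0.48 ± 0.16 and 0.42 ± 0.16, and the peroxidase Gpx2 gave 0.72 ± 0.27.

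Markers of the epithelium and of protein and energy metabolism also moved up in this comparison. Ribosomal proteins shifted up (21 of 22 above 0, median 0.25, camera adjusted p = 1.67e-07; adjusted p = 0.155 with an estimated correlation). Rpl19 gave 0.30 ± 0.09 and Rps3 0.35 ± 0.13. Oxidative phosphorylation genes shifted up (34 of 39 above 0, median 0.15, camera adjusted p = 1.69e-05; adjusted p = 0.406 with an estimated correlation). The complex III subunit Uqcrb gave 0.44 ± 0.12 and the succinate dehydrogenase subunit Sdhb 0.39 ± 0.13. Club cell markers shifted up (14 of 17 above 0, median 0.23, camera adjusted p = 4.54e-05; adjusted p = 0.104 with an estimated correlation). The secretoglobin Scgb1a1 gave 0.33 ± 0.16 and the retinal-oxidizing Aldh1a1 0.30 ± 0.12. Alveolar type 2 markers shifted up (18 of 22 above 0, median 0.18, camera adjusted p = 0.000172; adjusted p = 0.141 with an estimated correlation), but their median became -0.02 under quantile normalization (adjusted p = 0.839). Among them were the surfactant proteins Sftpa1 (0.29 ± 0.10) and Sftpc (0.36 ± 0.15) and the chitinase-like Chil1 (0.47 ± 0.13). Quantile normalization also weakened the ribosomal (adjusted p = 0.530), oxidative phosphorylation (adjusted p = 0.0977), club cell (adjusted p = 0.763) and NRF2 (adjusted p = 0.0562) shifts. In this comparison 3 probe sets rose and 0 fell, with 1103 at unadjusted p < 0.05 while 4 were called with the 3'/5' ratio as a covariate and 971, 387 up and 584 down, with the B1 signal as a covariate. DE2000_OVA replicate 4 was the array apart in that ratio and in B1. The call of Cd177 was lost without that array (1.63) and without air_OVA replicate 2 or 3 or DE2000_OVA replicate 3 (adjusted p from 0.0559 to 0.111 in these fits), that of Polr2j without any 1 of 6 of the 8 arrays, and all 3 when only the 2 groups were fitted. With the 3'/5' ratio and the B1 signal both as covariates only Pigr kept its call.

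With OVA, exhaust at 500 ug/m3 gave 0 calls in limma, and 125 probe sets had unadjusted p < 0.05. That is below the 679 expected without any effect. The fit shares 1 estimate of the spread per probe set with the saline arrays, whose 3'/5' ratios varied more. The genes with the smallest p were Fbxl6, a ubiquitin-ligase subunit (0.71 ± 0.19), the matrix-signalling Ccn1 (-0.49 ± 0.15), the sterol transporters Abcg8 (0.65 ± 0.20) and Abcg4 (0.46 ± 0.15), and the endosomal Ccdc93 (-0.47 ± 0.15), all at adjusted p = 1.0. Saa3 gave -0.30 ± 0.48, Retnla -0.12 ± 0.21, Chil3 -0.03 ± 0.16 and Cyp1a1 0.03 ± 0.28. Heat shock genes shifted up (13 of 19 above 0, median 0.09, camera adjusted p = 0.0239; adjusted p = 0.915 with an estimated correlation). The small chaperones Hspb8 and Hspb1 gave 0.40 ± 0.19 and 0.32 ± 0.20. Circadian clock genes shifted down (3 of 15 above 0, median -0.15, camera adjusted p = 0.0411; adjusted p = 0.453 with an estimated correlation). The output factor Dbp gave -0.73 ± 0.32 and the clock repressor Bhlhe40 -0.30 ± 0.14, and this call was lost with the 3'/5' covariate (adjusted p = 0.0596). No alternative gave a call for a gene in this comparison.

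Averaged over saline and OVA, DE 2000 raised 12 probe sets, among them those that speak for 9 genes. A pair of probe sets of Cp also passed (0.74, adjusted p = 0.0218, and 0.99, adjusted p = 0.0296). The probe set that speaks for Cp did not (0.86, adjusted p = 0.113). Cd177 rose 4.42-fold (2.14 ± 0.21, adjusted p = 9.50e-06), Pigr 2.81-fold (1.49 ± 0.15, adjusted p = 1.01e-05) and Lcn2 1.78-fold (0.83 ± 0.13, adjusted p = 0.00289), all with 8 arrays against 8. Retnla rose by 0.86 ± 0.15 (adjusted p = 0.0169) and Ifitm1 by 0.74 ± 0.11 (adjusted p = 0.00289). The smaller rises were those of Ppp1r3c, which targets a phosphatase to glycogen (0.60 ± 0.12, adjusted p = 0.0356), Polr2j (0.45 ± 0.08, adjusted p = 0.0306) and Nupr1, a stress-induced chromatin protein (0.44 ± 0.09, adjusted p = 0.0368). Saa3 gave 1.63 ± 0.34 (adjusted p = 0.0717).

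Acute phase genes shifted up in this average (10 of 12 above 0, median 0.27, camera adjusted p = 1.33e-06; adjusted p = 0.00763 with an estimated correlation). Of these, 1 was called over all genes, Lcn2, and 6 over the list alone, including Cp (0.86 ± 0.19) and Reg3g (2.18 ± 0.53). Circadian clock genes shifted down, with 0 of 15 above 0 (camera adjusted p = 4.04e-06; adjusted p = 0.00622 with an estimated correlation). Over the list alone 4 were called: Nr1d1 (-1.03 ± 0.29), Nr1d2 (-0.45 ± 0.13), Tef (-0.25 ± 0.07) and Dbp (-0.69 ± 0.23). Neutrophil markers shifted up (10 of 12 above 0, median 0.27, camera adjusted p = 0.000176; adjusted p = 0.0721 with an estimated correlation). Over the list alone 3 were called, and Pglyrp1 gave 0.70 ± 0.21. NRF2 targets shifted up (16 of 21 above 0, median 0.16, camera adjusted p = 0.000775; adjusted p = 0.0718 with an estimated correlation). Akr1b8 gave 0.41 ± 0.11 and the glutathione reductase Gsr 0.29 ± 0.12. Within the single arms at DE 2000, the neutrophil list was called only with saline, and the clock and NRF2 lists only with OVA. Targets of the aryl hydrocarbon receptor gave a median of -0.01 (3 of 6 above 0, camera adjusted p = 0.865). Cd177, Pigr, Lcn2 and Ifitm1 were called under every alternative. Retnla was lost without DE2000_saline replicate 3 (adjusted p = 0.0593), Ppp1r3c, Polr2j and Nupr1 were each lost without any 1 of at least 10 of the 16 arrays, Ppp1r3c and Nupr1 also with the replicate block (0.0742 and 0.0883). Array weights gave 22 calls, of which 6 fell, the B1 covariate gave 45, of which 18 fell, and 1021 probe sets had unadjusted p < 0.05.

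**Figure D3:**
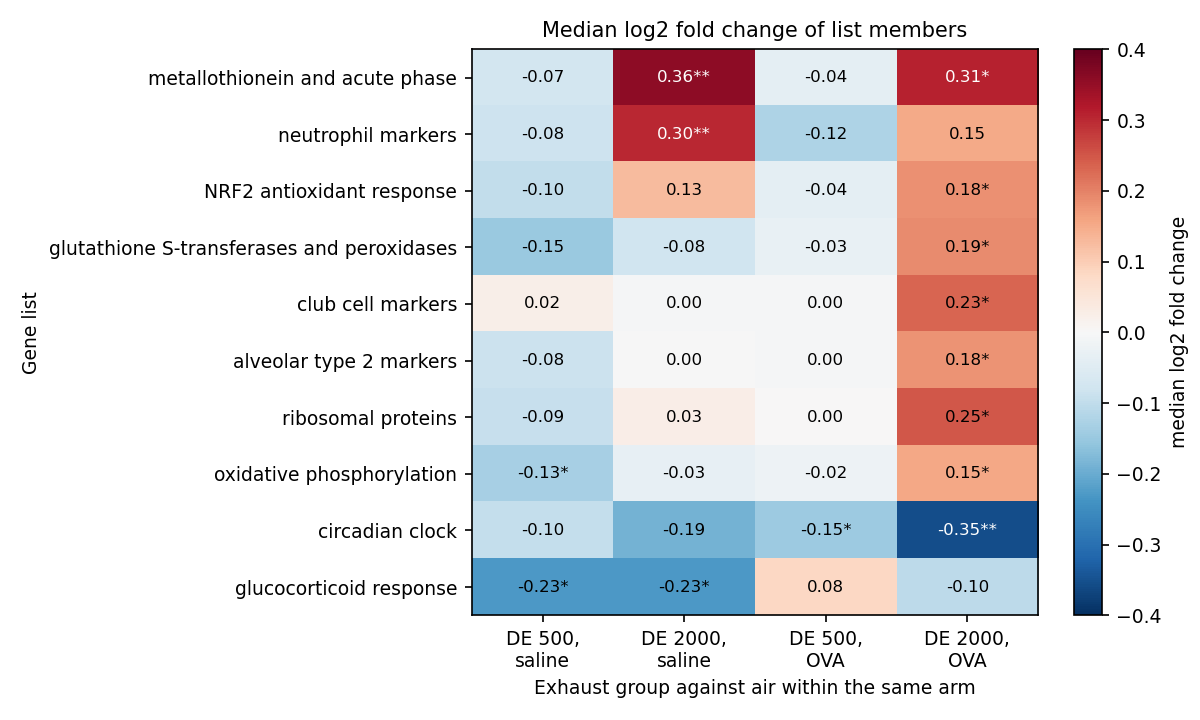
Median log2 fold change against air (color and number) of 10 gene lists (y axis) for each exhaust dose and arm (x axis); 1 star is camera adjusted p < 0.05 and 2 stars the same with an estimated correlation. The clock list fell by 0.35 at DE 2000 with OVA, and the alveolar type 2 median there changed from 0.18 to -0.02 under quantile normalization.

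Averaged over the arms, DE 500 gave 0 calls in limma, with 601 probe sets at unadjusted p < 0.05, below the 679 expected without any effect. The smallest p belonged to Tmod3 (0.62 ± 0.14), the exonuclease Xrn2 (0.36 ± 0.09), Tbx4 (0.45 ± 0.11), Fyttd1 (0.93 ± 0.22) and the interferon-induced GTPase Irgm1 (-0.40 ± 0.10), all at adjusted p = 0.906. Heat shock genes shifted up and oxidative phosphorylation genes down (camera adjusted p = 0.0429 for each; adjusted p = 0.859 with an estimated correlation). The chaperone Hspa1b gave 0.66 ± 0.33 and the complex I subunit Ndufb5 -0.22 ± 0.10, and each list had adjusted p = 0.0569 under median scaling.

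Set directly against DE 500 and averaged over the arms, DE 2000 gave 11 probe sets that were higher and 0 that were lower. Cd177 was higher by 2.26 ± 0.21 (adjusted p = 3.23e-06), Pigr by 1.59 ± 0.15 (adjusted p = 3.23e-06), Cp by 1.08 ± 0.19 (adjusted p = 0.0168), Lcn2 by 0.92 ± 0.13 (adjusted p = 0.000739), Ifitm1 by 0.68 ± 0.11 (adjusted p = 0.00796) and Prom1, a membrane protein of progenitor cells, by 0.71 ± 0.13 (adjusted p = 0.0198). Saa3 was higher by 1.73 ± 0.34 (adjusted p = 0.0498). Acute phase genes (11 of 12 above 0, median 0.34, camera adjusted p = 3.76e-07; adjusted p = 0.0104 with an estimated correlation), neutrophil markers (12 of 12 above 0, median 0.33, camera adjusted p = 1.30e-06; adjusted p = 0.0227 with an estimated correlation) and NRF2 targets (19 of 21 above 0, camera adjusted p = 5.69e-05; adjusted p = 0.0230 with an estimated correlation) were higher. Over their lists alone 6, 6 and 3 members were called, among them S100a9 (0.79 ± 0.23), the lactoferrin gene Ltf (0.61 ± 0.19), Akr1b8 (0.46 ± 0.11) and the carbonyl reductase Cbr3 (0.41 ± 0.12). With the 3'/5' covariate 321 probe sets were called, including all 11, and with the B1 covariate 242, of which 146 were lower. Cd177, Pigr, Lcn2 and Ifitm1 were called under every alternative, while Saa3 was lost under quantile normalization (adjusted p = 0.0648), with the replicate block (0.0853) and without any 1 of 12 of the 16 arrays. Cp and Prom1 were lost when only the 2 doses were fitted (adjusted p = 0.117 for each), with array weights (0.0563 and 0.111) and without any 1 of 4 and of 7 arrays, and Prom1 also with the replicate block (0.0501).

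OVA in air was accompanied by 2004 calls, 1035 up and 969 down, between arms that also differed in RNA quality. Xdh, which breaks purines down to uric acid, rose 8.50-fold (3.09 ± 0.42, adjusted p = 0.000399; 7.08 ± 0.36 in saline and 10.17 ± 1.06 in OVA, SD, n = 4 each). Tnxb, a matrix tenascin, rose by 2.05 ± 0.35 (adjusted p = 0.00234) and Col4a3, a collagen of basement membranes, by 2.17 ± 0.48 (adjusted p = 0.00900). The nuclear scaffold gene Safb2 fell by 1.72 ± 0.25 (adjusted p = 0.000496) and the zinc-finger repressor Zbtb20 fell by 1.81 ± 0.33 (adjusted p = 0.00448). Chil3 and Retnla, both induced in allergic lungs, gave -0.01 ± 0.16 (adjusted p = 0.960) and -0.03 ± 0.21 (adjusted p = 0.940).

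Further rises were those of the integrin Itga8 (2.96 ± 0.81, adjusted p = 0.0214) and the transcription factor Dach1 (2.49 ± 0.69, adjusted p = 0.0221). They also included the amino acid transporter Slc6a14 (2.01 ± 0.49, adjusted p = 0.0131), the vesicle GTPases Rab5c (2.00 ± 0.45, adjusted p = 0.00990) and Rab27b (1.89 ± 0.47, adjusted p = 0.0136), and the adenosine-producing Nt5e (1.89 ± 0.50, adjusted p = 0.0194). Further falls were those of the splicing gene Clasrp (-2.19 ± 0.70, adjusted p = 0.0389), the muscle glycogen synthase Gys1 (-1.56 ± 0.50, adjusted p = 0.0395), Arhgap31 (-1.54 ± 0.23, adjusted p = 0.000854) and Sh3bp1 (-1.40 ± 0.30, adjusted p = 0.00860). The proton-pump subunit Atp6v1c2 (-1.45 ± 0.39, adjusted p = 0.0200), the activin receptor Acvr2b (-1.39 ± 0.29, adjusted p = 0.00755) and the guidance molecule Sema6b (-1.65 ± 0.53, adjusted p = 0.0390) fell as well. Another probe set of Arhgap31 was called in the opposite direction. With the 3'/5' ratio as a covariate Xdh gave 3.24 (adjusted p = 0.000990), Tnxb 2.14 (adjusted p = 0.00533), Safb2 -1.19 (adjusted p = 0.000134), Itga8 1.09 (adjusted p = 0.0790), Dach1 1.16 (adjusted p = 0.218) and Nt5e 0.85 (adjusted p = 0.157). The calls of Slc6a14 (adjusted p = 0.0688), Rab27b (0.132), Clasrp (0.135), Gys1 (0.234), Sema6b (0.194), Atp6v1c2 (0.177) and Acvr2b (0.0609) were also lost with it, while those of Col4a3 (0.0150), Rab5c (0.0499), Zbtb20 (0.00609), Arhgap31 (0.00533) and Sh3bp1 (0.0282) were kept. With the B1 signal as a covariate these 5 were lost as well (adjusted p = 0.398, 0.121, 0.201, 0.0648 and 0.114), with Col4a3 at 0.68 and Zbtb20 at -0.85. The 3'/5' covariate left 240 calls, 88 up and 152 down, and 223 of them were among the 2004, and the B1 covariate left 28. The count was 985 without air_saline replicate 1, 450 without air_saline replicate 3, and 772, 1147 and 915 without air_OVA replicates 1, 3 and 4. Leaving out single arrays ended the calls of Sema6b (7 of 8 arrays), Gys1 (6), Clasrp (5), Itga8 (4), Dach1 (4), Atp6v1c2 (3), Nt5e (2) and Slc6a14 (1). A rise of Ralgapa1, a GTPase activator, was also called (adjusted p = 0.0489) and was lost without any 1 of the 8 arrays. A called fall of the ciliary Anks3 (adjusted p = 0.0285) was lost without any 1 of 3 arrays. No list was called (lowest camera adjusted p = 0.125), and of T helper 2 and allergic airway genes 5 of 12 were above 0, with a median of -0.02, a mean of 0.07 and 1 called up.

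Averaged over the 3 exposures, OVA was accompanied by 6284 calls, 3086 up and 3198 down, or 46.3% of probe sets. Xdh rose 9.52-fold (3.25 ± 0.24, adjusted p = 5.87e-09; 12 arrays against 12) and gave 3.40 with the 3'/5' covariate (adjusted p = 3.46e-07). Nt5e rose by 2.16 ± 0.29, Col4a3 by 1.74 ± 0.27 and Foxf1, a transcription factor of lung mesenchyme and capillaries, by 1.83 ± 0.30, and with the covariate they gave 1.14, 0.69 and 0.68 (adjusted p = 0.000765, 0.00385 and 0.00610). With the B1 signal as a covariate all 3 were lost (adjusted p = 0.566, 0.937 and 0.912). Falls included Fubp1, a single-strand DNA-binding regulator (-1.73 ± 0.16; -1.87 with the covariate, adjusted p = 3.61e-06), Zeb2, a repressor active in mesenchyme and myeloid cells (-1.60 ± 0.13; -1.25 with the covariate, adjusted p = 1.86e-06), Zbtb20 (-1.88 ± 0.19; -1.20 with the covariate) and the splicing factor Sfpq (-1.57 ± 0.22; -1.34 with the covariate). With the B1 covariate Zbtb20 gave -0.73 (adjusted p = 0.0604) and Sfpq -1.18 (adjusted p = 0.0872), and both calls were lost. Chil3 gave 0.12 ± 0.09 (adjusted p = 0.299). Retnla fell by 0.31 ± 0.12 (adjusted p = 0.0396), but gave -0.20 with the covariate (adjusted p = 0.428).

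Other large values shrank once the 3'/5' ratio was in the model. Itga8 rose by 2.61 ± 0.47 and gave 0.77 with the covariate. S1pr3, a receptor for sphingosine 1-phosphate, rose by 2.39 ± 0.55 and gave 0.58 (adjusted p = 0.441), and Dach1 rose by 1.88 ± 0.40 and gave 0.58 (adjusted p = 0.266). Ralgapa1, a GTPase activator, rose by 1.83 ± 0.36 and gave 0.57 (adjusted p = 0.182), and the deacetylase Sirt2 rose by 1.73 ± 0.38 and gave 0.41 (adjusted p = 0.388). The splicing gene Snrpd3 rose by 1.98 ± 0.25 while another of its probe sets was called down. Further falls were those of the bromodomain gene Brwd1 (-1.72 ± 0.26), the ciliary Anks3 (-1.68 ± 0.32), Arhgap31 (-1.65 ± 0.13, with another probe set called up), Phxr4 (-1.59 ± 0.35), the membrane adaptor Sntb2 (-1.53 ± 0.16) and the zinc-finger gene Zmym5 (-1.53 ± 0.13). With the 3'/5' covariate these 6 falls kept their calls, but with the B1 covariate Brwd1 gave -0.66 (adjusted p = 0.397), Anks3 -0.32 (0.778), Phxr4 -1.60 (0.167) and Sntb2 -0.63 (0.0917), and the call of Snrpd3 was lost as well (0.147). With the B1 covariate Itga8, S1pr3, Dach1, Ralgapa1 and Sirt2 had values below 0. The covariate left 1917 calls, 656 up and 1261 down, of which 1710 were among the 6284 in the same direction, and the B1 covariate left 557, 93 up and 464 down. No list was called without the covariate (lowest camera adjusted p = 0.209), although members were called, such as 1 up and 7 down of 15 clock genes, 9 up and 0 down of 17 mesothelial and fibroblast markers, and 5 up and 0 down of 12 chemokines, beside the 46.3% called over all probe sets.

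**Figure D4:**
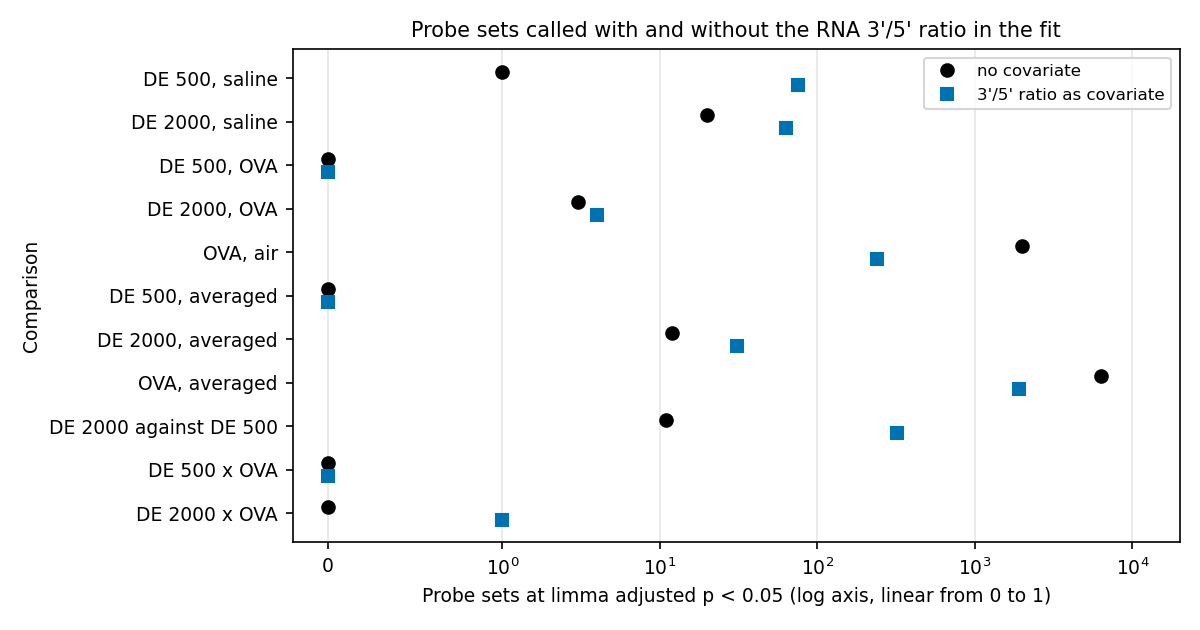
Probe sets called at adjusted p < 0.05 (x axis, count) in each comparison (y axis), without and with the 3'/5' ratio as a covariate. OVA averaged over exposures had 6284 calls without and 1917 with the covariate.

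The test of whether the effect of exhaust depends on OVA gave 0 calls in limma at either dose, with 419 probe sets at unadjusted p < 0.05 for DE 500 and 829 for DE 2000. The count for DE 500 is below the 679 expected without any effect. With the B1 covariate 181 were called at DE 2000, and without air_saline replicate 4 there were 64 at DE 2000 and 10 at DE 500. For DE 2000 the smallest p belonged to Tbx4 (-1.26 ± 0.22, adjusted p = 0.0852; adjusted p = 0.0476 with the 3'/5' covariate), the autophagy scaffold Wdfy3 (-1.52 ± 0.34) and Pgap2 (-1.33 ± 0.31), both at adjusted p = 0.298, the helicase Ddx10 (-0.98 ± 0.23, adjusted p = 0.330) and the zinc-finger gene Zfp109 (-0.99 ± 0.25, adjusted p = 0.363). For DE 500 it belonged to Tmod3 (-1.21 ± 0.28), Eif2ak2 (-1.28 ± 0.32), the adhesion molecules Alcam (-1.06 ± 0.29) and Nectin3 (-0.55 ± 0.15), and the phosphatase-like Hdhd3 (1.01 ± 0.28), all at adjusted p = 1.0. The shift of the neutrophil list differed between the arms at DE 2000 (median -0.35, camera adjusted p = 0.0199; adjusted p = 0.341 with an estimated correlation). That of the clock list did not pass (median -0.21, camera adjusted p = 0.0864), and neither did that of the acute phase list (median -0.14, camera adjusted p = 0.392).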

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

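The wrong-label test of DE2000_OVA replicate 4 was chosen only after its result was seen; the other tests in this part were set in advance. Within each group of 4, an array was set apart when its gap to the nearest other array, divided by the range of the group, passed the 95% limit of Dixon's test. Of 444 groups of 4 examined (70 genes and 4 array measures), 31 had such an array, while chance alone sets apart about 1 in 20, or 5%. All 13 cases in DE2000_OVA were replicate 4.

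DE2000_OVA replicate 4 lay apart in the 3'/5' ratios of Gapdh (Dixon ratio 0.889; 2.09 against -0.49 to -0.21) and actin (0.878), in the B1 signal (0.871) and in the score of the axis of largest variance (0.908). It also lay apart in the genes Dach1 (0.851), Foxf1 (0.875), Hmox1 (0.908; log2 signal 4.87 against 7.50 to 7.77), Itga8 (0.982; 7.33 against 10.81 to 10.87), Mt2 (0.892), Ralgapa1 (0.890), S1pr3 (0.902), Slc6a14 (0.855) and Sntb2 (0.928).

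Over all tested probe sets the mean squared deviation of this array from its group was 0.534, against a median of 0.121 and at most 0.377 for the 23 others. Slopes on the 3'/5' ratio, fitted without it, predicted 40.9% of that deviation (correlation 0.64 across probe sets, which are not independent replicates). RNA degradation may therefore account for part of it, and what the ratio does not measure cannot be told apart from a difference between lungs. A saline array under an OVA label is argued against: on a scale from 0 (saline) to 1 (OVA), after removal of the slope on the ratio, it scored 0.74, against -0.26 to -0.06 in DE2000_saline and 1.08 to 1.2 in the other DE2000_OVA arrays. No biological explanation for a single array was tested.

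The remaining arrays apart were not weighed further. In air_OVA replicate 2 these were the score of the axis of largest variance (0.895), Col4a3 (0.889), Foxf1 (0.845), Nt5e (0.863), Saa3 (0.855) and Tmod3 (0.850). In air_OVA replicate 4 they were Ccn1 (0.870) and Gclc (0.831), and in air_OVA replicate 3 Eif2ak2 (0.851) and Wdfy3 (0.854). DE500_OVA replicate 4 was apart in Gys1 (0.857) and DE500_saline replicate 2 in Hdhd3 (0.871). DE2000_saline replicate 1 was apart in Alcam (0.905), Sirt2 (0.855) and Zfp109 (0.890), and replicate 2 in Phxr4 (0.917). In air_saline, replicate 4 was apart in Zeb2 (0.845) and replicate 3 in Zfp109 (0.932).

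The effect of exhaust on 11 gene lists differed between the saline and OVA arms by the interaction test with the preset correlation, and for none with an estimated correlation. At DE 500 with OVA, immediate early genes were lower (camera adjusted p = 0.00170; 0.508 with an estimated correlation), and glucocorticoid-responsive genes (5.99e-05; 0.795) and adipose markers (0.0157; 0.795) were higher. At DE 2000 with OVA, oxidative phosphorylation (6.82e-05; 0.363), glutathione (0.000963; 0.236), ribosomal (0.000963; 0.420), tricarboxylic acid cycle (0.0161; 0.220), interferon (0.0199; 0.341) and mesothelial and fibroblast genes (0.0260; 0.341) were higher and neutrophil markers lower (0.0199; 0.341). Alveolar type 2 markers were higher as well (0.0161; 0.363), but under quantile normalization that shift vanished (median 0.01, adjusted p = 0.978).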

How the results depend on the processing

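The fits with the 3'/5' ratio, the B1 signal or both as covariates, and that with the 3'/5' ratio without DE2000_OVA replicate 4, were chosen only after the results were seen; the others were set in advance. Cd177, Pigr, Lcn2 and Ifitm1 at DE 2000 averaged over the arms kept their direction and their call in every alternative run (Cd177 1.80 to 2.30, Pigr 1.38 to 1.56, Lcn2 0.76 to 0.91, Ifitm1 0.69 to 0.80). The same held for Xdh with OVA averaged over the exposures (2.67 to 3.41), and for the acute phase list (median 0.18 to 0.31) and the clock list (-0.24 to -0.15) at DE 2000 averaged over the arms. Quantile normalization, no filter and the replicate block left all 11 counts of calls within 1.5 times.

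DE 500 in saline had 1 call. It had 0 under median scaling, when only the groups compared were fitted, with array weights and without the trend, 6 with 1 probe set per gene, where fewer probe sets share the adjustment, 7 with the stricter filter and 10 with the pseudocount. Fitting only the groups compared gave 12 calls for DE 2000 in saline, 0 for DE 2000 with OVA, 3359 for OVA in air and 6 for DE 2000 against DE 500. Array weights gave 138 for DE 2000 in saline, 3687 for OVA in air, 22 for DE 2000 averaged and 1 for the interaction of DE 2000 and OVA. Using 1 probe set per gene gave 9 for DE 2000 in saline, 1091 for OVA in air, 3650 for OVA averaged, since fewer probe sets are tested, and 1 for the interaction of DE 2000 and OVA.

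The 3'/5' covariate gave 75 calls for DE 500 in saline, 63 for DE 2000 in saline, 240 for OVA in air, 31 for DE 2000 averaged, 1917 for OVA averaged, 321 for DE 2000 against DE 500 and 1 for the interaction of DE 2000 and OVA. Without DE2000_OVA replicate 4 as well, these were 213, 140, 516, 58, 1900, 260 and 2, with 1 for DE 500 averaged. The B1 covariate gave 23, 38, 28, 45, 557, 242 and 181, with 971 for DE 2000 with OVA. Both covariates gave 66, 46, 52, 19, 229 and 291 for the same comparisons up to DE 2000 against DE 500, and 1 for DE 2000 with OVA. Apart from the tests of the difference between the arms given under the other observations, the cause was not tested.

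Leaving out 1 array gave 0 to 101 calls for DE 500 in saline, 4 to 106 for DE 2000 in saline, 0 to 0 for DE 500 with OVA, 1 to 7 for DE 2000 with OVA, 450 to 1958 for OVA in air, 0 to 10 for DE 500 averaged, 5 to 29 for DE 2000 averaged, 5644 to 6833 for OVA averaged, 8 to 14 for DE 2000 against DE 500, 0 to 10 for the interaction at DE 500 and 0 to 64 for that at DE 2000. The highest counts for both doses in saline, both averages over the arms and both interactions came without air_saline replicate 4. The lowest count for DE 2000 in saline came without air_saline replicate 1, DE2000_saline replicate 3 or DE2000_saline replicate 4, and the lowest for OVA in air without air_saline replicate 3. The cause was not tested.

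Among lists and named genes the following results reversed. Quantile normalization turned the median of the alveolar type 2 list to -0.0195 at DE 2000 with OVA and to -0.0151 averaged over the arms, and for the interaction of DE 2000 and OVA, where the median was 0.00572, it turned the direction of the test. With the B1 covariate OVA averaged over the exposures gave -0.54 for Itga8, -0.76 for S1pr3, -0.25 for Dach1, -0.0877 for Foxf1, -0.20 for Ralgapa1, -0.0578 for Col4a3 and -0.30 for Sirt2, and with both covariates 0.35 for Anks3. The correlation of the DE 500 and DE 2000 effects in OVA became -0.13 on average over 6 splits of the air arrays. Each dose then had its own part of them as control, which removes what a shared control puts into both. The splits ranged from -0.29 to 0.02 (SD 0.14), so the sign is uncertain. Apart from these splits of the air arrays the cause was not tested.

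Of 50 calls of lists, 42 were lost with an estimated correlation, all in the same direction, and under quantile normalization 17 were lost in the same direction and 3 were the reversals given above. Both covariates together ended 19 calls of lists, array weights 10, the B1 covariate 8 and the 3'/5' covariate 3. Of 67 calls of named genes, 17 were lost with the 3'/5' covariate, 26 with the B1 covariate and 34 with both, besides the reversals given above. In the fits without 1 array, 106 calls of lists were lost and 845 list results stayed as they were, and 161 calls of named genes were lost and 2119 results stayed as they were. Only 50 of 72 list results and 67 of 170 named gene results were called in the main fit. The others had no call to lose and count among those that stayed, unless they gained one. Median shifts of all genes under either scaling stayed at or below 0.07. Probe sets with a mean signal under 138 were tested only in the fit with no filter, and no background level was measured.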

Other observations

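With the 3'/5' ratio as a covariate, 5 gene lists passed camera for OVA averaged over the exposures, which none did without it. Circadian clock genes shifted down (adjusted p = 0.0166; adjusted p = 0.244 with an estimated correlation), among them the output factors Hlf (-0.82, adjusted p = 0.000139) and Tef (-0.35, adjusted p = 0.00227) and the period gene Per1 (-0.60, adjusted p = 0.00119). Tricarboxylic acid cycle genes shifted up (adjusted p = 0.0166; adjusted p = 0.244 with an estimated correlation), among them the isocitrate dehydrogenases Idh3a (0.59, adjusted p = 2.73e-05) and Idh2 (0.55, adjusted p = 0.00527). Mesothelial and fibroblast markers shifted up (adjusted p = 0.0221; adjusted p = 0.244 with an estimated correlation), with the proteoglycan Ogn at 0.47 (adjusted p = 8.05e-05) and the plasminogen-binding Clec3b at 1.23 (adjusted p = 0.00405). Club cell markers shifted up (adjusted p = 0.0166; adjusted p = 0.244 with an estimated correlation), with the transferase Gsta3 at 0.48 (adjusted p = 0.0464), and so did oxidative phosphorylation genes (adjusted p = 0.0166; adjusted p = 0.746 with an estimated correlation), with cytochrome c, Cycs, at 0.62 (adjusted p = 0.000875). A difference in the time of day of sampling, which moves clock genes, was not tested, here or for exhaust.

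Across 8315 genes, which are not independent replicates, the effects of DE 500 and DE 2000 correlated at 0.54 in saline and at 0.21 in OVA. A shared control alone gave simulated medians of 0.40 (-0.28 to 0.80) and 0.22 (-0.52 to 0.66) over 100 simulations, so both correlations lie within what it can give. The air arrays were also split so that each dose had its own part as control. Over 6 splits the correlations then averaged 0.11 (-0.13 to 0.27) and -0.13 (-0.29 to 0.02). The effects of DE 2000 in saline and in OVA, which share no array, correlated at 0.12, at 0.03 without the filter and at 0.16 with the stricter filter. Of the 20 probe sets that rose with DE 2000 in saline, 2 were also called in OVA, where 0.00442 would be shared by chance, and 10 had values above 0.

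The counts of other splits of the arrays were set in advance; the tests of RNA quality, allergic inflammation, neutrophils and dose below were chosen only after the result was seen. Every comparison was refitted to other splits of the same arrays.

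For DE 2000 in saline chance is argued against: 1 of 35 splits, the real one, gave as many as 20 calls, and the highest other gave 3. The same holds for DE 2000 averaged over the arms (1 of 100 splits, 12 calls against at most 0). It holds as well for OVA in air (1 of 35, 2004 against 0) and OVA averaged (1 of 100, 6284 against 0). These shares are the smallest that 35 or 100 splits can give. They were not adjusted over the 11 comparisons, so they do not exclude chance. For DE 2000 against DE 500, 3 of 100 splits gave as many as 11 calls, but the highest gave 715. Chance was not argued against for DE 500 in saline (11 of 35, 1 call against 3061) or DE 2000 with OVA (3 of 35, 3 against 10). For DE 500 with OVA, DE 500 averaged and the interactions at DE 500 and DE 2000 the real split had 0 calls. Every split then gives as many, so the test could not decide. The highest other splits there gave 3, 702, 821 and 1 calls, in that order. The splits with 3061, 702, 715 and 821 calls put DE500_saline replicates 1 and 4 apart from replicates 2 and 3, which points to a structure of the samples that follows the 3'/5' ratio. Within that group, replicates 1 and 4 against 2 and 3 gave 3439 calls. With the ratio as a covariate DE 500 in saline gave 75 calls and DE 2000 against DE 500 gave 321.

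The OVA and saline arms differed at 6284 probe sets, and along with treatment they differed in the 3'/5' ratio, in B1 signal and in the hybridization controls added to every array (-0.37, exact permutation p = 0.00573). RNA degradation is argued against as the whole cause only as far as a straight slope on the ratio measures it. With the ratio as a covariate 1917 probe sets were called. DE500_OVA against DE500_saline replicates 2 and 3 gave 62 calls, 61 of them also called with the covariate. These replicates have low ratios (0.33 and 0.10, against -0.04 to 0.12 in DE500_OVA). They also entered the covariate fit, so the overlap is not independent. Their B1 signals (12.08 and 12.30) lay above those of DE500_OVA (11.41 to 11.94), so this comparison does not separate treatment from B1. For the 4572 calls that ended, the median absolute log2 fold change fell from 0.43 to 0.19 while the SE went from 0.118 to 0.126, so the calls ended because the difference shrank, and 437 of them changed sign. With the B1 signal added 229 were called, 205 of them among the 6284 in the same direction. Over the 6284 the median absolute log2 fold change was 0.25 with the ratio and 0.26 with both, while the SE went from 0.125 to 0.220. A wider SE alone raises absolute values, so these medians do not show whether differences shrank further. Anks3, for example, kept its fall with the ratio but gave 0.35 with both covariates. Degradation together with carried-over repeat-rich RNA cannot be told apart from treatment. Allergic airway inflammation is argued against only as far as Chil3 and the 12 tested genes of the T helper 2 and allergic airway list show it. OVA was given on 3 days, and whether the mice were sensitized before or challenged later is not described here. If they were not, these genes need not have responded, so the values say nothing on allergy in sensitized lungs. The fold change of Chil3 had an upper 95% limit of 1.25 without covariates and at most 1.60 with the ratio, the B1 signal or both. The median of the list was at most 0.06 in these fits. Il4, Il13, Ccl11 and Clca1 lay below the signal limit and were not tested. Other responses to OVA and an unlabelled difference in sample handling between the arms stay open and may both contribute.

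Within the saline arm the score of the axis of largest variance, which held 49.1% of the variance, correlated with the 3'/5' ratio at r = 0.93 (permutation p = 1e-05, the smallest the permutations can give) and rho = 0.90 (p = 0.00015), and at r = 0.94 without the 2 arrays farthest out. In the OVA arm r was 0.97 (permutation p = 0.0284) and rho 0.07 (p = 0.834), a correlation that rests on DE2000_OVA replicate 4, without which r was 0.14 (p = 0.683); without the 2 arrays farthest out r was 0.36. A total of 5146 probe sets had a slope on the ratio within groups.

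The rise of Cd177, Pigr, Lcn2 and other genes at DE 2000 is not explained by RNA degradation as the ratio measures it. All 12 probe sets called over the arms stayed called with the ratio as a covariate. More neutrophils as the whole cause is argued against with OVA, where the abundant neutrophil transcripts S100a8 and S100a9 changed by 0.02 ± 0.34 on average, with an upper 95% limit of 0.73, while Cd177 rose by 1.90 with a lower limit of 1.24. With saline it stays open, since they changed by 1.06 ± 0.34 with an upper limit of 1.78, while Cd177 rose by 2.39 with a lower limit of 1.73. Cd177, Pigr, Lcn2 and Ifitm1 were called higher at DE 2000 than at DE 500 in a comparison made over all probe sets, under every alternative. The 20 probe sets called in saline were on average 0.19 ± 0.06 higher at DE 2000 than at DE 500 in the OVA arrays, which did not choose them (exact permutation p = 0.0571; 9 of 20 above 0), so a response to the dose stays open for these as a set, and which cells express these genes was not tested.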
